A study of Homo sapiens with 12 samples.

How the data were processed

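RNA from RCC4 cells was measured on 12 Affymetrix 3′ expression arrays, 3 in each of 4 groups: non-targeting siRNA (siNT) with vehicle, siNT with erastin, siRNA against WWTR1 (siTAZ) with vehicle, and siTAZ with erastin. RNA was collected after 2 days of siRNA and 7 hours of DMSO or 1 µM erastin. TAZ here is the protein of WWTR1 and not tafazzin, which once had the same symbol. Groups were taken from the sample titles, and 0 columns could not be mapped. The submitters describe the replicates as biological triplicates.

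The values used are the log2 probe set signals deposited by the authors, made with Affymetrix Expression Console and RMA per the submitters' processing notes; the versions are not given in the sources used here. The array medians of 6.48 to 6.54 and the range of 2.02 to 14.4 are those of signals that were normalised between arrays. The series text also describes a transformation of each gene against the mean of the siNT arrays, which the deposited values do not show, so the signals were taken as untransformed. The number of arrays limits the precision. No genome build is given in the sources used here, so genes are identified by symbol and no positions are given. Of 22277 probe sets, 62 controls, 1043 that match several genes and 2108 without a listed gene were left out. The other 19064 covered 11963 genes, of which 4310 had more than 1 probe set; the probe set with the highest mean over all 12 arrays stood for its gene. Genes of a list without a probe set were not analysed here.

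All 12 arrays entered 1 fit with a mean for each group in limma 3.58.1 (R 4.3.3), with moderated variances (8 residual and 3.90 prior degrees of freedom). The 7 comparisons were siTAZ against siNT in vehicle and under erastin, erastin against vehicle in siNT and in siTAZ cells, the difference between the erastin responses (the interaction), and the averages of the siTAZ and of the erastin effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, without a minimum fold change. With 3 arrays against 3, an exact permutation test of one gene cannot give a p under 0.1, so no such test was made per comparison. WWTR1 was compared over 6 against 6 arrays with a two-sided exact permutation test. On simulated data with the same layout, 78% of genes with a true log2 change of 0.5 and 98% of those with a change of 1 were recovered for siTAZ in vehicle, 80% and 99% for erastin in siNT cells, and 2.72% to 3.95% of gene calls were false over the settings tested. With the ATF4 list shifted by 0.3, camera called it for siTAZ in vehicle, for erastin in siNT cells and for the interaction, and for erastin in siNT cells 1 of the 2 lists called was false. The simulated noise was drawn for each gene alone. On the real arrays a single principal component held 35.3% of the within-group variance. These rates therefore may not hold for the real arrays.

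The 26 gene lists were written from general knowledge and tested with limma camera at an inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. They were the YAP/TAZ target signature, Hippo components, ferroptosis suppressors and promoters, ATF4-driven genes, unfolded protein response, NRF2, cholesterol synthesis, S phase, G2 and M phase, hypoxia-inducible factor, p53, type I interferon, NF-kB, immediate early, extracellular matrix, actin and serum response factor, epithelial, heat shock, metallothionein, ribosomal protein and oxidative phosphorylation genes, and markers of leukocytes, endothelial cells, erythroid cells and fibroblasts. Members were counted as risen or fallen over all genes and adjusted over the list alone. Some genes stand in several lists, so the lists are not independent. SLC7A11 is in the ATF4, NRF2 and ferroptosis suppressor lists. STC2 is in the ATF4 and hypoxia-inducible factor lists, and ATF3 in the ATF4 and immediate early lists. Camera with a correlation estimated per list, and the directional form of fry, were the alternatives.

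The text could name 19 fixed genes: WWTR1, YAP1, CCN1, CCN2, ANKRD1, AMOTL2, EMP1, NOX4, SLC7A11, GPX4, ACSL4, TFRC, CHAC1, ATF3, DDIT3, ASNS, TRIB3, HMOX1 and VEGFA. For each pairwise comparison it could also name the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, for the interaction 5 per sign, and for each list up to 4 members with the largest called change per comparison. Genes outside this rule are named only where a count of 5 or fewer asks for it. The groups, comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except where stated.

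The alternatives were centring each array on its median, a second quantile normalisation, leaving out genes with a mean under the 25th or the 50th percentile, the mean of all probe sets or each probe set on its own, the trend and robust settings, array weights, only the 2 compared groups in the fit, a log2 fold change of at least 1 in addition, a term for the replicate number, and leaving out each array in turn. A covariate, the 3′ minus 5′ log2 signal of the actin control probe sets, was chosen after seeing that it differed between arrays. Leaving out each array for the lists was also added then. Where leaving out an array leaves 2 in a group, the spread is that pooled over the groups.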

Results

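RNA from RCC4 cells was measured on 12 expression arrays. RCC4 is an established human clear cell renal carcinoma line that lacks functional VHL, so its hypoxia-inducible factors are active in normal oxygen. The cells received either a non-targeting control siRNA (siNT) or an siRNA against WWTR1, the gene for the Hippo pathway coactivator TAZ (siTAZ). After 2 days they were given DMSO vehicle or 1 µM erastin for 7 hours. Erastin blocks the cystine/glutamate antiporter, whose transport subunit is SLC7A11, and can drive cells into ferroptosis, an iron-dependent death by lipid peroxidation. Each of the 4 groups held 3 arrays, described by the submitters as biological triplicates. The deposited log2 signals ran from 2.02 to 14.4, and array medians lay between 6.48 and 6.54. Arrays of the same group correlated at 0.9962 to 0.9987, whereas an siNT and an siTAZ array correlated at 0.9914 to 0.9937. The number of arrays limits the precision of every value. Genes are given by symbol with the log2 fold change of the probe set with the highest mean signal, ± the standard error of the limma fit with n = 3 arrays per group, and a gene is said to have risen or fallen where its Benjamini-Hochberg adjusted p in limma was under 0.05.

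WWTR1 was low on every siTAZ array. Its brightest probe set had a log2 signal of 12.28 ± 0.06 (SD, n = 6) on siNT arrays and 9.25 ± 0.14 (SD, n = 6) on siTAZ arrays. This left 12.2% of the control signal, 8.19-fold less, with an exact two-sided permutation p of 0.0022, the smallest that 6 arrays against 6 can give. The other WWTR1 probe sets had 10.1% and 8.15% of the control signal left. The fall was −2.94 ± 0.07 in vehicle and −3.12 ± 0.07 under erastin. YAP1, the paralogue of WWTR1, had log2 fold changes of −0.02 ± 0.07 and −0.01 ± 0.07 and did not pass the test in either medium.

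**Figure D1:**
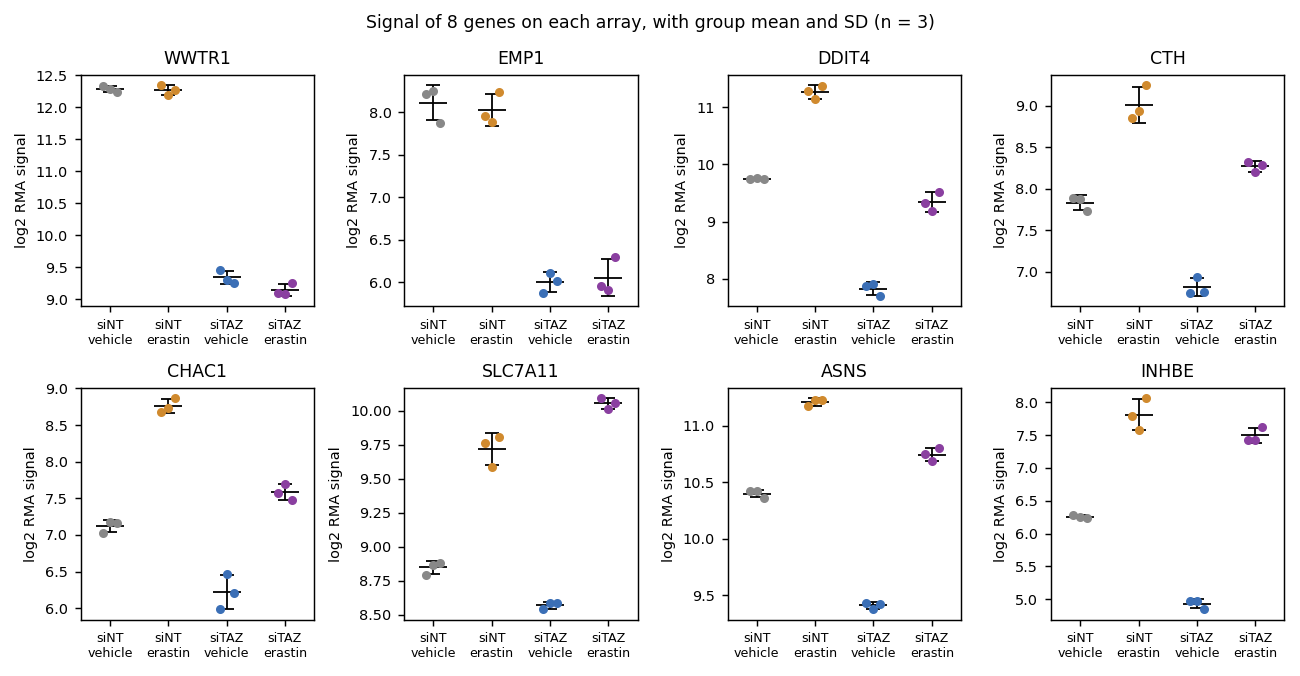
Log2 RMA signal of 8 genes on each of the 12 arrays, one panel per gene, with the 4 groups on the horizontal axis; points are arrays, the bar is the group mean and the whiskers are the SD (n = 3). WWTR1 and EMP1 were lower on siTAZ arrays, while the signals of DDIT4, CTH, CHAC1, SLC7A11, ASNS and INHBE were higher on erastin arrays than on vehicle arrays of the same siRNA.

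The first comparison asks which transcripts change when WWTR1 is silenced in vehicle. The chemokine gene CXCL14 rose most, by 2.47 ± 0.10 or 5.54-fold, from a log2 signal of 6.80 ± 0.14 to 9.27 ± 0.13 (SD, n = 3). The epithelial transcription factor gene ELF3 rose by 1.77 ± 0.06 with SH3YL1 at 1.77 ± 0.13, DENND5B at 1.75 ± 0.15 and PLSCR4 at 1.65 ± 0.11. After WWTR1 itself, the membrane protein gene EMP1 fell most, by −2.11 ± 0.13 or 4.32-fold. The next falls were SCG5 at −1.96 ± 0.08, TNFRSF11B, the gene for the decoy receptor osteoprotegerin, at −1.95 ± 0.11 to a signal in the range of markers of other cell types, which makes it a lower bound, and DDIT4, an inhibitor of mTORC1 signalling, at −1.93 ± 0.09. ADM, which encodes the vasodilator adrenomedullin, fell by −1.86 ± 0.09, EVI2A by −1.86 ± 0.09, the lipoprotein lipase inhibitor gene ANGPTL4 by −1.70 ± 0.11 and the insulin receptor substrate gene IRS2 by −1.61 ± 0.09. In limma, 3419 of 11963 genes changed, of which 1755 rose and 1664 fell. Of these, 157 changed at least 2-fold, 94 upward and 63 downward. In 43.8% of genes the 3 values of one group all lay above those of the other, against 10% by chance. TECPR2 (1.94 ± 0.11) also rose, but its other probe set gave 0.21. ZBTB20 rose by 1.89 ± 0.11, while its dimmest probe set gave 0.05. EMP1 fell on a second probe set too (−1.31), while its dimmest gave −0.14.

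Among gene lists fixed beforehand, the list of amino acid and integrated stress response genes attributed to ATF4 stood out. ATF4-driven is used here as the name of that list, and the activity of ATF4 was not measured. Of 40 measured members, 31 fell and only ATF3 rose, by 0.26 ± 0.06; adjusted over the list alone, 32 fell and 2 rose. Besides DDIT4, the largest falls were those of the secreted glycoprotein gene STC2 at −1.23 ± 0.06, the pseudokinase gene TRIB3 at −1.04 ± 0.05 and CTH, the cystathionine gamma-lyase that makes cysteine, at −1.02 ± 0.10. ASNS, which encodes asparagine synthetase, fell by −0.99 ± 0.05, the glutathione-degrading enzyme gene CHAC1 by −0.90 ± 0.11 and the stress transcription factor gene DDIT3 by −0.40 ± 0.09. The list median was −0.38, with a limma camera adjusted p of 3.76e-14 over 26 lists, and 0.0294 with an estimated correlation.

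Cell cycle genes were lower as well. Of 33 genes of G2 and M phase 24 fell and 0 rose (25 and 1 adjusted over the list alone), among them the mitotic kinesin genes KIF23 at −0.77 ± 0.09 and KIF20A at −0.68 ± 0.08 and the mitotic kinase gene AURKB at −0.56 ± 0.07. The camera adjusted p was 8.99e-09, and 0.0294 with an estimated correlation. Of 31 S phase genes 13 fell and 0 rose (14 and 0 adjusted over the list alone), including RRM2, a subunit of ribonucleotide reductase, at −0.73 ± 0.05, CCNE1 (cyclin E) at −0.45 ± 0.06 and E2F1 at −0.35 ± 0.08. This list had a camera adjusted p of 0.000332, which became an adjusted p of 0.258 with an estimated correlation. Its count of falls was 8 without siNT vehicle replicate 1, siTAZ vehicle replicate 2 or siTAZ vehicle replicate 3.

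Targets of hypoxia-inducible factors fell in part. Of 29 measured, 14 fell and 3 rose (14 and 5 adjusted over the list alone). ADM, ANGPTL4 and STC2 were among the falls, as were the glucose transporter gene SLC2A3 at −1.24 ± 0.07 and the angiogenic factor gene VEGFA at −0.71 ± 0.07. The 3 that rose, named because they were few and after their values were seen, were CA12 (0.52), LOX (0.34) and ALDOC (0.29). The camera adjusted p was 0.00186, and the adjusted p was 0.271 with an estimated correlation. A dimmer SLC2A3 probe set gave −0.06. Of 8 metallothionein genes, which encode metal-binding proteins, 6 fell and 0 rose, also adjusted over the list alone, for example MT1X by −0.71 ± 0.07 and MT2A by −0.56 ± 0.05. Their camera adjusted p was 0.000119, and the adjusted p was 0.258 with an estimated correlation. The members are near-identical in sequence, and their probe sets cannot be told apart with certainty.

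Extracellular matrix and mesenchymal genes moved the other way. Of 32 measured, 12 rose and 1 fell (13 and 2 adjusted over the list alone). The fall was that of COL6A3, whose signals of 4.75 and 3.95 were as dim as those of marker lists of other cell types (4.33 to 4.89), so its size is not given. Fibronectin, FN1, rose by 0.92 ± 0.06 and the mesenchymal transcription factor gene SNAI2 by 0.85 ± 0.13. The camera adjusted p was 0.0111, and the adjusted p was 0.258 with an estimated correlation; the list median of 0.11 was 0.16 without siNT vehicle replicate 2 or siTAZ vehicle replicate 1. Of 21 actin cytoskeleton and serum response factor targets, 7 rose and 0 fell (7 and 1 adjusted over the list alone), led by FILIP1L at 1.42 ± 0.05, with the calponin gene CNN1 at 0.80 ± 0.14 and the myosin light chain gene MYL9 at 0.67 ± 0.10. The smooth muscle actin gene ACTA2 rose by 0.79 ± 0.06 on its brighter probe set, and its other probe set gave −0.06. The camera adjusted p of this list was 0.0188, the adjusted p was 0.258 with an estimated correlation, and the call was lost without siNT vehicle replicate 3 (adjusted p = 0.0795).

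The signature of YAP/TAZ target genes was mixed. Of 19 measured, 6 fell and 2 rose (7 and 3 adjusted over the list alone). The falls included the tissue factor gene F3 at −1.50 ± 0.07, CCN2 (connective tissue growth factor) at −0.63 ± 0.10, FJX1 at −0.59 ± 0.07, ANKRD1 at −0.47 ± 0.11 and CCN1 at −0.27 ± 0.06. AMOTL2, at −0.07 ± 0.06, did not pass the test. The 2 that rose, named after their values were seen, were NT5E (0.39) and the dim DOCK5 (0.28). As a list the signature was not called by camera (median −0.07, adjusted p = 0.32). Of 22 Hippo pathway components 5 rose and 3 fell (6 and 3 adjusted over the list alone), among them TEAD1, a DNA-binding partner of TAZ, at 0.59 ± 0.10, the kinase gene STK3 at 0.42 ± 0.07 and the atypical cadherin gene FAT4 at −0.43 ± 0.11. That list was not called either (adjusted p = 0.775).

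Genes linked to ferroptosis changed in both directions. Of 17 suppressors 7 fell and 3 rose, the same counts adjusted over the list alone. GCH1, which makes tetrahydrobiopterin, fell by −1.19 ± 0.13, the thioredoxin reductase gene TXNRD1 by −0.38 ± 0.05 and SLC7A11 by −0.28 ± 0.06. NFE2L2, the gene for NRF2, rose by 0.48 ± 0.06. The lipid peroxide-reducing enzyme gene GPX4 rose by 0.24 ± 0.07, but its call was lost without siNT vehicle replicate 1 or 2 or any of the 3 siTAZ vehicle arrays, where it was 0.19 to 0.25. The suppressors had a median of 0.03 and a mean of −0.11 (camera adjusted p = 0.428). Of 23 promoters 7 fell and 4 rose, again the same adjusted over the list alone. ACSL4, which activates polyunsaturated fatty acids, rose by 0.87 ± 0.15, whereas EMP1, the haem oxygenase gene HMOX1 (−0.83 ± 0.06) and the fatty acid elongase gene ELOVL5 (−0.86 ± 0.05) fell. Dimmer ELOVL5 probe sets gave −0.04 and −0.14. The NADPH oxidase gene NOX4 had signals of 3.47 and 3.94, under those of marker lists of other cell types (4.33 to 4.89), so no size is given for it here or in the other comparisons; its call was lost without siNT vehicle replicate 1 (adjusted p = 0.12) or siTAZ vehicle replicate 2 (adjusted p = 0.0984). The transferrin receptor gene TFRC, at −0.02 ± 0.05, did not pass the test. The promoters were not called as a list (adjusted p = 0.296).

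The next comparison asks what silencing of WWTR1 does in erastin-treated cells. CXCL14 was again the largest rise, at 2.62 ± 0.10 or 6.16-fold, with further rises of DENND5B at 1.76 ± 0.15 and ARHGAP5 at 1.62 ± 0.14. EMP1 fell by −1.97 ± 0.13 or 3.91-fold, DDIT4 by −1.93 ± 0.09, TNFRSF11B by −1.85 ± 0.11 (again a lower bound), ADM by −1.82 ± 0.09, SCG5 by −1.69 ± 0.08, the zinc transporter gene SLC39A6 by −1.64 ± 0.05 and F3 by −1.59 ± 0.07. In limma, 3369 genes changed, 1867 upward and 1502 downward, and 145 changed at least 2-fold (84 up, 61 down). In 38.8% of genes the groups did not overlap, against 10% by chance. The actin 3′ minus 5′ control signal, a sign of RNA quality, was 2.26 ± 0.69 (SD, n = 3) on siNT erastin arrays and 3.25 ± 0.33 (SD, n = 3) on siTAZ erastin arrays. With that signal as a covariate, 2556 genes were called, 2040 of them also called without it. The same measure from the GAPDH control probe sets was 0.15 ± 0.08 on siNT erastin and 0.20 ± 0.06 on siTAZ erastin arrays. In vehicle it was 0.18 ± 0.07 and 0.20 ± 0.07 (SD, n = 3). The difference between groups was thus seen with actin and not with GAPDH.

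Effects of siTAZ were alike with and without erastin. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.877 and Spearman's rho of 0.729, and the contrasts share no arrays. Of the genes called in both, 1395 rose in both (274 for independent lists), 1144 fell in both (209 for independent lists) and 2 went opposite ways. These were SLC7A11, at −0.28 ± 0.06 in vehicle and 0.33 ± 0.06 under erastin, and JAG1, a Notch ligand gene named after its values were seen, at 0.17 and −0.25. For SLC7A11 under erastin a second probe set gave 0.20, a dim one gave −0.21, and the mean of all probe sets (0.11) was not called.

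**Figure D2:**
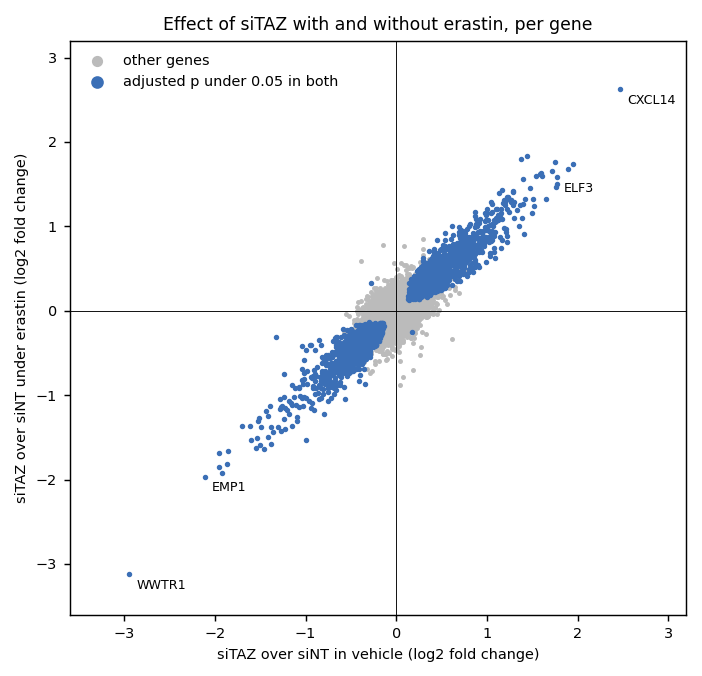
Log2 fold change of siTAZ over siNT in vehicle (horizontal axis) and under erastin (vertical axis) for each of 11963 genes; blue points passed adjusted p 0.05 in both comparisons and grey points did not. The points lie along the diagonal (Pearson's r = 0.877), with WWTR1 and EMP1 low and CXCL14 high in both.

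Gene groups under erastin followed the vehicle pattern in part. Of 40 ATF4-driven genes 26 fell and 3 rose (27 and 3 adjusted over the list alone), with a median of −0.22 and a camera adjusted p of 3.9e-10, and an adjusted p of 0.11 with an estimated correlation. CHAC1 fell by −1.17 ± 0.11, STC2 by −0.75 ± 0.06, CTH by −0.74 ± 0.10, TRIB3 by −0.69 ± 0.05 and ASNS by −0.47 ± 0.05. The 3 that rose were the dim CBS (0.41), PSPH (0.35) and SLC7A11, the first 2 named after their values were seen. ATF3, at −0.02 ± 0.06, did not pass the test. Of 29 hypoxia-inducible factor targets 15 fell and 4 rose, also adjusted over the list alone (adjusted p = 7.79e-05, and 0.231 with an estimated correlation), with SLC2A3 at −1.02 ± 0.07, BNIP3L at −0.86 ± 0.06 and VEGFA at −0.54 ± 0.07; the count of rises was 2 without siNT erastin replicate 2 or siTAZ erastin replicate 1 or 3. Of 8 metallothionein genes 6 fell and 0 rose, also adjusted over the list alone (adjusted p = 7.79e-05, and 0.288 with an estimated correlation). Of 33 genes of G2 and M phase 16 fell, and MKI67 rose by 0.31 (19 and 3 adjusted over the list alone, adjusted p = 0.000104, and 0.196 with an estimated correlation). With the actin covariate 17 ATF4-driven genes and 10 genes of G2 and M phase fell. The extracellular matrix and actin cytoskeleton lists, called upward in vehicle, were not called under erastin, also not with that covariate (camera adjusted p = 0.151 and 0.175).

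A further 3 groups were called under erastin with weaker footing. The YAP/TAZ signature had a median of −0.14, with 6 of 19 falling and 2 rising (7 and 2 adjusted over the list alone, camera adjusted p = 0.0162, and 0.309 with an estimated correlation). CCN2 fell by −0.58 ± 0.10, FJX1 by −0.59 ± 0.07, CCN1 by −0.38 ± 0.06 and ANKRD1 by −0.54 ± 0.11, and NT5E (0.50) and DOCK5 (0.28) rose; AMOTL2, at −0.14 ± 0.06, did not pass the test. Of 24 immediate early genes 11 fell and 2 rose (12 and 2 adjusted over the list alone, adjusted p = 0.0112, and 0.231 with an estimated correlation), for example KLF4 by −0.98 ± 0.14, while EGR1 rose by 0.42 ± 0.06 and JUND by 0.24. Of 31 S phase genes 8 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0112, and 0.409 with an estimated correlation), among them RRM2 at −0.64 ± 0.05; 4 fell without siNT erastin replicate 3 or siTAZ erastin replicate 2, and 5 without replicate 1 of either group. With the actin signal as a covariate none of them was called (adjusted p = 0.215, 0.175 and 0.359), with medians of −0.12 for YAP/TAZ, −0.15 for the immediate early genes (−0.21 without it) and −0.03 for S phase (−0.08 without it). ANKRD1 lost its call there too, and the S phase call was also lost without siTAZ erastin replicate 2 (adjusted p = 0.0526). Among ferroptosis genes, GCH1 (−1.06 ± 0.13) and HMOX1 (−1.03 ± 0.06) fell and ACSL4 (0.60 ± 0.15) and GPX4 (0.39 ± 0.07) rose, GPX4 without a call under the actin covariate. NOX4 and TFRC (−0.02 ± 0.05) did not pass the test. Neither the suppressors nor the promoters were called as a list, also not with the actin covariate (camera adjusted p = 0.741 and 0.175).

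**Figure D3:**
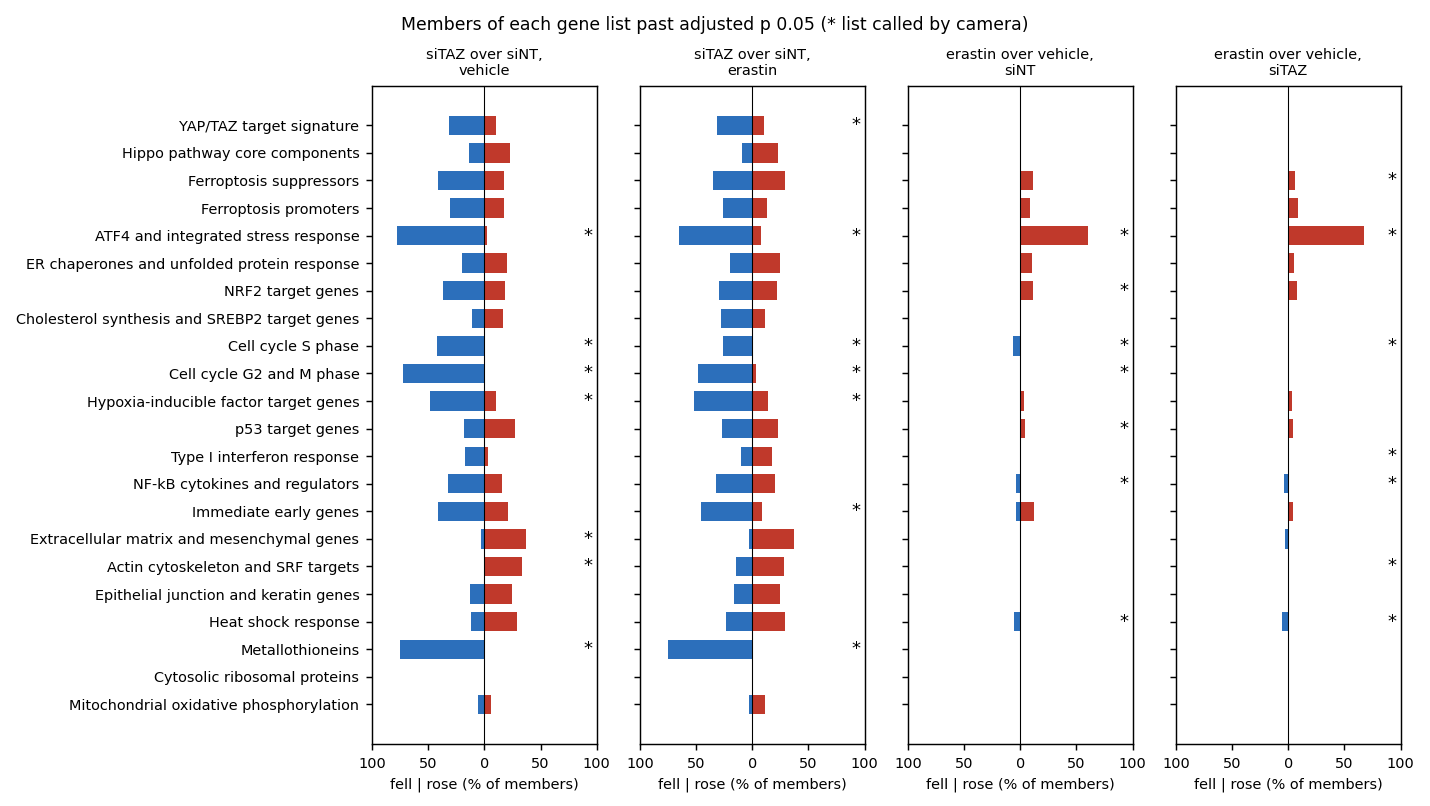
Percentage of measured members of each of 22 gene lists that rose (red, to the right) or fell (blue, to the left) past adjusted p 0.05 in limma, for the 4 pairwise comparisons; an asterisk marks lists called by camera with the preset correlation. The ATF4 list points left with siTAZ (31 of 40 fell in vehicle) and right with erastin (24 of 40 rose in siNT cells and 27 of 40 in siTAZ cells).

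The erastin response of control cells was small and led by ATF4-driven genes. In siNT cells CHAC1 rose by 1.63 ± 0.11 or 3.10-fold, from a log2 signal of 7.13 ± 0.08 to 8.76 ± 0.09 (SD, n = 3). INHBE, an inhibin beta subunit gene, rose by 1.55 ± 0.10, DDIT4 by 1.52 ± 0.09 and CTH by 1.18 ± 0.10, and these 4 were the only genes called at 2-fold or more. SLC7A11, the target of erastin, rose by 0.87 ± 0.06, ASNS by 0.81 ± 0.05, STC2 by 0.77 ± 0.06, ATF3 by 0.77 ± 0.06, the mitochondrial enzyme gene PCK2 by 0.74 ± 0.09 and HMOX1 by 0.69 ± 0.06. The uPA receptor gene PLAUR fell by −0.46 ± 0.05, the growth factor gene HBEGF by −0.46 ± 0.06, the phosphatase gene DUSP7 by −0.52 ± 0.06 and CD83 by −0.43 ± 0.05; the dimmest probe sets of DUSP7, HBEGF and PLAUR gave −0.17, −0.21 and −0.14. In limma 96 genes changed, 63 upward and 33 downward, and in 14.4% of genes the groups did not overlap, against 10% by chance. Without siNT vehicle replicate 1, 2 or 3 the count was 34, 33 and 37, and without siNT erastin replicate 1 or 2 it was 30 and 53. It was 39 with a replicate term, 186 with trend and robust settings and 324 with array weights. The actin 3′ minus 5′ signal was 2.68 ± 0.28 in vehicle and 2.26 ± 0.69 under erastin (SD, n = 3), with siNT erastin replicate 3 at 1.49.

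Of the 40 ATF4-driven genes 24 rose and 0 fell in siNT cells, and 35 rose adjusted over the list alone. The list median was 0.32, the camera adjusted p 3.35e-58, and the adjusted p 0.000306 with an estimated correlation. DDIT3 rose by 0.60 ± 0.09, with an adjusted p of 0.0551 without siNT erastin replicate 1, and TRIB3 rose by 0.36 ± 0.05. The count of rises was 14, 13 and 15 without siNT vehicle replicate 1, 2 or 3, and 12 without siNT erastin replicate 1. Of 27 NRF2 targets SLC7A11, HMOX1 and AKR1C1 (0.38 ± 0.07) rose and 0 fell, with 7 rising adjusted over the list alone; the camera adjusted p was 8.11e-06, and 0.0206 with an estimated correlation. The NRF2 list median of 0.05 was 0.02 without siNT vehicle replicate 1, and the dimmest AKR1C1 probe set gave −0.13. The AKR1C1 call was lost without siNT vehicle replicate 1, 2 or 3 or siNT erastin replicate 1 or 2 (adjusted p = 0.0562 to 0.130). Of 22 p53 targets only PMAIP1, the gene for the apoptosis inducer NOXA, rose, by 0.48 ± 0.10 (5 adjusted over the list alone; adjusted p = 3.27e-07, and 0.0254 with an estimated correlation). The call of PMAIP1 itself was lost without any of the 6 arrays (adjusted p = 0.0565 to 0.156).

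Several lists shifted downward with erastin in siNT cells although few members passed the test singly. Of 31 S phase genes CCNE1 (−0.32 ± 0.06) and GINS1 (−0.26 ± 0.05) fell, or 10 adjusted over the list alone, with a median of −0.14 and a camera adjusted p of 2.57e-13. Of 33 genes of G2 and M phase 0 passed, also adjusted over the list alone, with a median of −0.11 and an adjusted p of 1.91e-07. Of 25 NF-kB cytokines and regulators NFKBIE (−0.31 ± 0.06) fell, or 9 falls and 1 rise adjusted over the list alone, with a median of −0.16 and an adjusted p of 1e-06. These 3 lists had adjusted p = 0.0206 with an estimated correlation. Of 17 heat shock genes DNAJB1 (−0.26 ± 0.05) fell, or 2 adjusted over the list alone, with an adjusted p of 0.000511 and an adjusted p of 0.0797 with an estimated correlation. The calls of CCNE1, GINS1, NFKBIE and DNAJB1 were lost without siNT vehicle replicate 1, 2 or 3 or siNT erastin replicate 1 or 2 (adjusted p = 0.0652 to 0.189). ACSL4 (−0.03 ± 0.15), GPX4 (0.01 ± 0.07), TFRC (0.06 ± 0.05), NOX4, VEGFA (0.10 ± 0.07), CCN1 (0.09 ± 0.06) and CCN2 (0.17 ± 0.10) did not pass the test.

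In siTAZ cells erastin raised the same kind of genes. INHBE rose by 2.57 ± 0.10 or 5.92-fold, from 4.93 ± 0.07 to 7.50 ± 0.12 (SD, n = 3), a start near the level of markers of other cell types that makes the rise a lower bound. DDIT4 rose by 1.52 ± 0.09, SLC7A11 by 1.48 ± 0.06, CTH by 1.46 ± 0.10, PCK2 by 1.36 ± 0.09, CHAC1 by 1.36 ± 0.11, ASNS by 1.34 ± 0.05, STC2 by 1.25 ± 0.06 and the stress protein gene NUPR1 by 1.05 ± 0.10. A dim SLC7A11 probe set gave 0.36. In limma 67 genes changed, 55 upward and 12 downward, of which 9 rose and 0 fell at least 2-fold. In 20.7% of genes the groups did not overlap, against 10% by chance. Falls were small: EFNB2 at −0.46 ± 0.08, CXCL8 at −0.41 ± 0.07 and HBEGF at −0.41 ± 0.06. The call of HBEGF was lost without siTAZ vehicle replicate 1 or 2 or siTAZ erastin replicate 3 (adjusted p = 0.0885, 0.0554 and 0.0752). The calls of CXCL8 and EFNB2 were lost in at least 4 of the 6 fits without an array (adjusted p = 0.0527 to 0.094). The count of changed genes was 30, 41 and 37 without siTAZ vehicle replicate 1, 2 or 3, and 35, 41 and 34 without siTAZ erastin replicate 1, 2 or 3. The actin 3′ minus 5′ signal was 2.65 ± 0.04 in vehicle and 3.25 ± 0.33 under erastin (SD, n = 3); with it as a covariate 45 genes changed, 44 upward and 1 downward, and 37 of them were called without it too.

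Of the 40 ATF4-driven genes 27 rose and 0 fell in siTAZ cells, and 35 rose adjusted over the list alone. The median was 0.49, the camera adjusted p 3.94e-70, and the adjusted p 0.00015 with an estimated correlation. Among them were the mitochondrial folate enzyme gene MTHFD2 at 0.98 ± 0.06, TRIB3 at 0.71 ± 0.05, DDIT3 at 0.64 ± 0.09, the cysteinyl-tRNA synthetase gene CARS1 at 0.62 ± 0.05 and ATF3 at 0.49 ± 0.06. The other calls were lost with an estimated correlation. Of 31 S phase genes 0 passed (3 fell adjusted over the list alone; median −0.09, or −0.05 without siTAZ erastin replicate 2; camera adjusted p = 1.66e-06, and adjusted p = 0.0906 with an estimated correlation). Of 17 heat shock genes CHORDC1 (−0.42 ± 0.08) fell, or 5 adjusted over the list alone (adjusted p = 1.43e-05, and adjusted p = 0.0619 with an estimated correlation); the CHORDC1 call was lost without any of the 6 arrays (adjusted p = 0.0951 to 0.249). Of 25 NF-kB genes CXCL8 fell, or 4 adjusted over the list alone (adjusted p = 0.000145, and adjusted p = 0.0619 with an estimated correlation). Of 21 actin cytoskeleton genes 0 passed, with 2 falls adjusted over the list alone (adjusted p = 0.00201, and adjusted p = 0.0906 with an estimated correlation). With the actin 3′ minus 5′ covariate the S phase median was −0.05 (camera adjusted p = 0.00131).

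Besides the ATF4 list, 2 lists shifted upward in siTAZ cells, but the second of them shares its only called member, SLC7A11, with the ATF4 list. Of 29 type I interferon response genes 0 passed, while 9 rose adjusted over the list alone; the median was 0.07, or 0.16 with the actin covariate (camera adjusted p = 1.02e-06, 1 rose), 0.12 without siTAZ vehicle replicate 2 and 0.11 without siTAZ erastin replicate 3 (camera adjusted p = 0.000263, and adjusted p = 0.268 with an estimated correlation). Of 17 ferroptosis suppressors SLC7A11 rose, or 2 adjusted over the list alone; the median was 0.07, or 0.03 without siTAZ erastin replicate 3 (adjusted p = 0.00986, and adjusted p = 0.0906 with an estimated correlation). HMOX1 rose by 0.49 ± 0.06. ACSL4 (−0.30 ± 0.15), GPX4 (0.16 ± 0.07), TFRC (0.06 ± 0.05), NOX4 and VEGFA (0.27 ± 0.07) did not pass the test.

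Erastin effects in siNT and siTAZ cells correlated weakly across genes, with Pearson's r of 0.293 and Spearman's rho of 0.166, and the contrasts share no arrays. With the actin covariate r was 0.0873, but that fit uses the same slope for both contrasts. The mean actin signal went from 2.68 to 2.26 with erastin in siNT cells and from 2.65 to 3.25 in siTAZ cells. The slope therefore shifts the 2 effects of a gene in opposite directions, and this lower r does not show that the responses differ. Of the genes called in both, 29 rose in both (0.290 for independent lists), 4 fell in both (0.0331 for independent lists) and 0 went opposite ways. The 4 were HBEGF, DUSP7, PLAUR and FHOD1; in siTAZ cells the calls of DUSP7, PLAUR and FHOD1 were lost without any of the 6 arrays (adjusted p = 0.117 to 0.201). Of the 96 genes called in siNT cells, 92.7% had the same direction in siTAZ cells.

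The test of the difference asks whether siTAZ alters the erastin response. In limma 0 genes were called, while 764 of 11963 (6.39%) had an unadjusted p under 0.05. INHBE (at least 1.01 ± 0.14, given its dim start in siTAZ cells), SLC7A11 (0.61 ± 0.09) and ASNS (0.52 ± 0.07) each had an adjusted p of 0.0583, and were called when arrays were centred on their medians or dim genes were left out at the 25th percentile. The trend and robust setting of limma called 10 genes, and 0 were called with the actin covariate. For CHAC1 the difference was −0.27 ± 0.15, for ATF3 −0.27 ± 0.08, for HMOX1 −0.20 ± 0.08 and for DDIT3 0.03 ± 0.13. On simulated data with the same layout, 49% of genes with a true difference of 0.5 and 97% of those with a difference of 1 were recovered. The simulated noise was independent between genes, so the real share may differ.

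In camera, 4 lists differed in their erastin response. The ATF4-driven genes rose more in siTAZ cells, by a median of 0.12 with 31 of 40 members positive (camera adjusted p = 1.64e-06, and 0.173 with an estimated correlation); adjusted over the list alone, 10 were higher and 1 lower. Their mean log2 signal was 9.76 ± 0.02 in siNT vehicle, 10.21 ± 0.03 in siNT erastin, 9.32 ± 0.01 in siTAZ vehicle and 9.89 ± 0.02 in siTAZ erastin (SD, n = 3). Genes of G2 and M phase differed by a median of 0.11 with 28 of 33 positive (adjusted p = 5.97e-05, and 0.173 with an estimated correlation). The p53 targets and the immediate early genes each differed by −0.08, with 16 of 22 and 16 of 24 negative (adjusted p = 0.0073 for both, and 0.293 and 0.228 with an estimated correlation). With an estimated correlation all 4 calls were lost. With the actin covariate the calls of the p53 targets (adjusted p = 0.878) and the immediate early genes (adjusted p = 0.272) were lost. The p53 call was also lost without siNT erastin replicate 3 (median −0.03, adjusted p = 0.0784) or siTAZ erastin replicate 2 (median −0.04, adjusted p = 0.104). The immediate early median was −0.13 without siNT erastin replicate 2, −0.12 without siTAZ erastin replicate 3 and −0.05 without siNT erastin replicate 3, and its call was lost on the mean of all probe sets (adjusted p = 0.061).

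**Figure D4:**
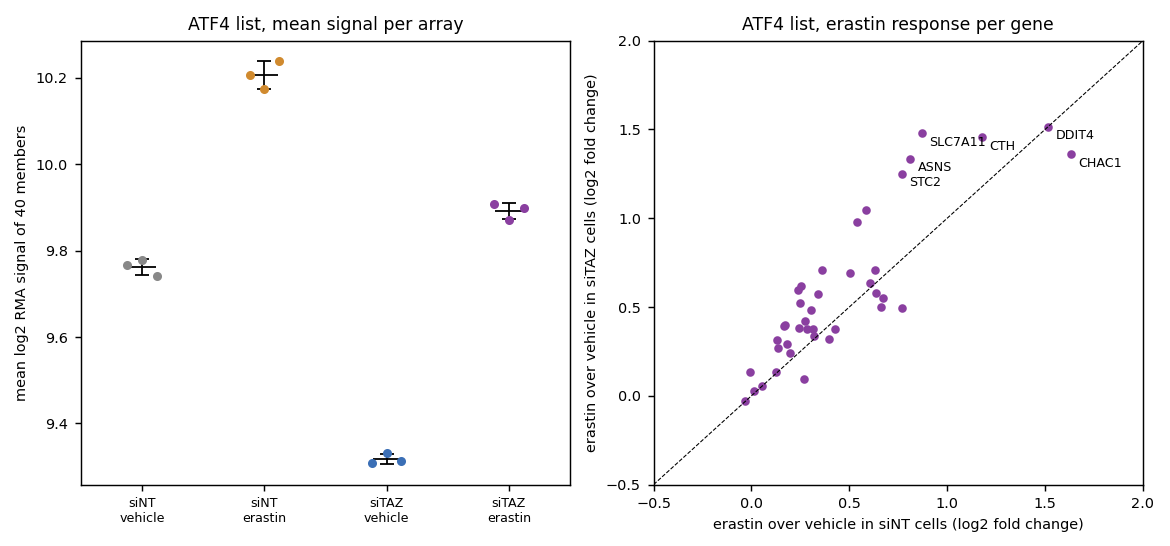
Left, mean log2 RMA signal of the 40 measured ATF4 list members on each array, with group mean and SD (n = 3); right, log2 fold change of erastin over vehicle in siNT cells (horizontal axis) and siTAZ cells (vertical axis) for each member, with the dashed line of equal response. The list mean was 9.76 in siNT vehicle and 9.32 in siTAZ vehicle, and 31 of 40 members lie above the line.

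Averaged over both media, siTAZ changed 4530 genes in limma, 2385 upward and 2145 downward. Averaged over both siRNAs, erastin changed 227 genes, 129 upward and 98 downward; the count was 129 without siNT vehicle replicate 1 or 2, 126 and 132 without siTAZ vehicle replicate 2 or 3, and 139 without siTAZ erastin replicate 1. Markers of leukocytes (19 measured), endothelial cells (15) and erythroid cells (8) gave 0 calls in each of the 4 pairwise comparisons, also adjusted over the list alone. With the actin covariate, 1 leukocyte and 2 endothelial markers fell with siTAZ under erastin, and camera called both lists upward for erastin in siNT cells (medians 0.10, adjusted p = 0.035 and 0.0466) and downward for the interaction (medians −0.16 and −0.15, adjusted p = 0.0267). Fibroblast markers (14) gave 1 call without the covariate, FBLN1 at 0.21 ± 0.07 with siTAZ under erastin, whose call was lost adjusted over the list alone and without 5 of the 6 arrays (adjusted p = 0.0694 to 0.177). Of 28 cytosolic ribosomal protein genes 0 changed in any of them.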

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

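Of the tests given here, those of the interferon response, of RNA quality (with the covariate fit of a relabelled split), of off-target effects and of single arrays were chosen only after the result was seen; the relabelled splits and the signal ceiling test were chosen before. The response to erastin differed between siTAZ and siNT cells for 4 gene lists by the test of that difference itself, although 0 single genes were called in limma and camera with an estimated correlation called none of the 4 (adjusted p = 0.173, 0.173, 0.293 and 0.228 for the ATF4, G2 and M phase, p53 and immediate early lists). The ATF4-driven genes differed by a median of 0.121 and the genes of G2 and M phase by 0.107 on the log2 scale. The p53 targets differed by −0.0770 and the immediate early genes by −0.0769.

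Splits of the array labels were used to ask whether grouping by luck gives as many called genes. For each pairwise comparison 10 splits exist, too few for a share under 0.05. The real split called 3419 genes for siTAZ in vehicle, where the highest other split called 0, and 3369 for siTAZ under erastin, again against 0. For erastin in siNT cells the values were 96 and 5, and in siTAZ cells 67 and 0; in each of these 4 comparisons only 1 of 10 splits, the real one, reached the count. Averaged over both media, 1 of 100 splits, the real one, gave as many genes as the real 4530 for siTAZ (highest other 1). For the averaged erastin effect 2 of 100 reached the real 227, the real split and 1 with other labels. Both shares lie under 0.05, so a lucky grouping is unlikely as the source of either count. It is not excluded for erastin, where that other split called more genes than the real one. The split above 227 called 336 genes. It exchanged replicate 3 of siNT vehicle with replicate 3 of siNT erastin, whose actin 3′ minus 5′ signals were 2.97 and 1.49, and 38 of its genes were called by the real split too. With the actin signal as a covariate this split called 51 genes and the real one 283. For the interaction all 100 splits had at least the real count of 0, as any split must, so they decide nothing there. The highest, 1479, exchanged siRNA labels among the erastin-treated arrays, so that the effect of siTAZ itself entered the difference, which is a structure of the samples.

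Silencing of WWTR1 changed 3419 genes in vehicle, and technical sources were weighed against loss of TAZ. Both groups received siRNA, so an interferon response common to both cancels in this comparison and cannot be seen. A stronger response to the siTAZ than to the siNT reagent would raise the interferon list, whose median in vehicle was −0.0865. The SE of the list's mean change, taken over the 29 genes with their estimated correlation, is 0.0959. It measures the spread between genes and not between arrays. The mean log2 signal of the list was 7.41 ± 0.01 on siNT vehicle and 7.32 ± 0.03 on siTAZ vehicle arrays (SD, n = 3). These values argue against a rise of the list as a whole in vehicle. A rise of single members is not excluded. The actin 3′ minus 5′ signal was alike in vehicle, 2.68 ± 0.28 and 2.65 ± 0.04 (SD, n = 3), so the 99.7% of called genes (3410) that were called again with it as a covariate decide little on RNA quality. Under erastin, where it was 2.26 ± 0.69 and 3.25 ± 0.33, 60.6% (2040 of 3369) were called again, which argues against RNA quality as the whole source there and leaves it open for the others. The GAPDH control signal was alike under erastin, 0.15 ± 0.08 and 0.20 ± 0.06 (SD, n = 3). This does not set the actin signal aside, as the first principal component within groups followed it (absolute Pearson's r of 0.824). An off-target effect of the siRNA cannot be told apart from loss of TAZ, because only 1 siRNA reagent against WWTR1 and no rescue was measured. Of the YAP/TAZ signature 31.6% fell in vehicle, against 13.9% of all other genes (two-sided exact Fisher p = 0.0388, which takes genes as independent), but camera did not call that list (adjusted p = 0.32, and 0.651 with an estimated correlation), so this does not settle it.

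The larger rise of the ATF4-driven genes in siTAZ cells started from a lower level, 9.32 against 9.76 in vehicle, and ended at 9.89 against 10.21. No single array accounts for it, as the lowest median difference over the 12 fits without 1 array was 0.0919, with a highest camera adjusted p of 0.00189. RNA quality is argued against as the whole source, since the median was 0.122 with the actin covariate (camera adjusted p = 9.68e-10). These calls rest on the preset correlation, as the list was not called with an estimated one (adjusted p = 0.173). A ceiling on bright signals could shrink the rise in siNT cells and stays open: the 21 members under 11 log2 units differed by a median of 0.0626, at the 89.5 percentile of 10000 random lists. A biological difference, a stronger response from a lower start, is a further open explanation. The same covariate also moved marker lists of other cell types, leukocytes to −0.156 and endothelial cells to −0.148 (camera adjusted p = 0.0267 for both), so a list call with it is weak evidence on its own.

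The genes of G2 and M phase, 28 of 33 positive, were called in each of the 12 fits without 1 array and with the actin covariate (adjusted p = 2.2e-06), but not with an estimated correlation (adjusted p = 0.173), and technical sources were not weighed further. The p53 targets lost their call with that covariate (adjusted p = 0.878) and the immediate early genes too (adjusted p = 0.272), so a part of RNA quality in these differences is not excluded.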

How the results depend on the processing

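The actin covariate, leaving out arrays for the lists, and the correlations with array weights or with each probe set on its own were chosen only after the result was seen. The fall of WWTR1 was called in each setting, and the counts for siTAZ in vehicle stayed within 1.5 times the reported one except with a minimum fold change. Where a value moved, the cause was not tested unless the setting itself gives it (fewer genes or arrays, or a stricter rule). With a log2 fold change of at least 1 the counts were 157 and 145 for siTAZ in vehicle and under erastin, 4 and 9 for erastin in siNT and siTAZ cells, and 143 and 8 for the averaged siTAZ and erastin effects. With each probe set on its own, 5064 probe sets were called for siTAZ under erastin, 7171 for its average and 62 for erastin in siNT cells. For erastin in siNT cells, in siTAZ cells and on average, the counts were 222, 157 and 419 for genes over the median of mean signals, 186, 164 and 358 with trend and robust settings, 324, 166 and 679 with array weights, and 39, 34 and 141 with a replicate term. No pairing of the arrays by replicate number was detected: 4 of 18 same-number pairs correlated above 0.1 (median −0.0608). Only 3 of 12 arrays correlated best with an array of their own number. A batch shared by arrays of the same number is not excluded by this. With only the 2 compared groups in the fit 15 genes were called for erastin in siNT cells. The interaction had 3 calls after median centring, a second quantile normalisation, the 25th percentile filter or array weights, 8 with the median filter and 10 with trend and robust settings. It kept 0 calls with a replicate term, with the mean of all probe sets and with the actin covariate.

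The correlation of the siTAZ effects was 0.907 and 0.927 with the 25th percentile and median filters, and 0.841 both by probe set and with the actin covariate. That of the erastin effects was 0.394 with the median filter, 0.176 by probe set, 0.410 with array weights and 0.0873 with the covariate. The covariate fit uses the same slope for both contrasts, so its value cannot be set beside the others. Lists called numbered 2, 0, 1 and 0 with an estimated correlation (siTAZ in vehicle, siTAZ under erastin, erastin in siTAZ cells, interaction) and 16, 15, 11 and 2 with fry. With the covariate they were 4 for siTAZ under erastin and 7 for the interaction (ATF4, G2 and M phase, S phase, interferon and ferroptosis suppressors upward, leukocyte and endothelial markers downward), and 7 for the interaction after median centring.

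Leaving out 1 array at a time gave 2809 to 3030 genes for siTAZ in vehicle, 2775 to 3236 under erastin and 4174 to 4769 on average, and 30 to 65, 30 to 41 and 126 to 295 for erastin in siNT cells, in siTAZ cells and on average. The interaction had 0 to 1, the 1 without siNT erastin replicate 3. WWTR1 was at −3.06 to −3.01, the correlations at 0.841 to 0.885 and 0.157 to 0.399, and lists called at 6 to 7, 6 to 8, 7 to 10, 7 to 12 and 4 to 7 in the order siTAZ in vehicle, siTAZ under erastin, erastin in siNT cells, erastin in siTAZ cells and interaction.

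Sign changes were counted only for named genes called in the main fit or in the alternative. Of the fits without an array, only the one with the highest adjusted p was looked at. Within these bounds single named genes changed sign only on their least alike probe set, and none was called on it. With siTAZ in vehicle these were ACTA2 (−0.0645), AKR1C1 (−0.104), MDM2 (−0.0176), MT1G (0.00127), SC5D (−0.00736) and SEC24D (−0.0141). With siTAZ under erastin they were AKR1C1 (−0.00628), ELOVL5 (0.179), FBLN1 (−0.0922), FGFR3 (−0.197), HMGCS1 (−0.153), MDM2 (−0.0694), MT1G (0.0290), SC5D (−0.0123) and SLC7A11 (−0.207). With erastin they were AKR1C1 (−0.130) in siNT cells, and DUSP7 (0.0590) and PLAUR (0.0498) in siTAZ cells. Of the named calls, 29 were lost with the covariate, 26 with the replicate term and 17 with the mean of all probe sets. Without some array 39 were lost. On the least alike probe set 50 were lost with the sign kept, and the 18 that changed sign were lost as well. There 65 comparisons of a named gene kept their call or their lack of one. Dim probe sets limit what these signals show.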

Other observations

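Of the tests given here, only the simulation that shares control arrays and exchanges siTAZ effects between genes was chosen after the result was seen. With siTAZ in vehicle, several inflammatory genes fell. Of 25 NF-kB cytokines and regulators 8 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.32). The interleukin gene IL6 fell by −0.93, the chemokine gene CXCL1 by −0.89 and CXCL3 by −0.52, while CCL2 rose by 0.61. Of 29 type I interferon response genes 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.32), with ISG15 at −0.67 and TRIM22 at 0.44. Immediate early genes went both ways, with 10 of 24 falling and 5 rising (10 and 6 adjusted over the list alone, adjusted p = 0.378); EGR1 rose by 0.79, and the transcription factor genes KLF4 (−0.81) and FOSL1 (−0.53) and the phosphatase gene DUSP6 (−0.44) fell. Among 24 epithelial junction and keratin genes 6 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.327), with ELF3 rising and the keratin gene KRT18 (−1.06), the claudin gene CLDN4 (−0.85) and the desmoplakin gene DSP (−0.35) falling.

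Stress and metabolic lists other than ATF4 were mixed in the same comparison. Of 27 NRF2 targets 10 fell and 5 rose, also adjusted over the list alone (adjusted p = 0.683), with AKR1C3 at 1.06 and UGDH at −0.75. Of 20 unfolded protein response genes 4 rose and 4 fell, again the same adjusted over the list alone (adjusted p = 0.604), EDEM1 by 0.89 and the chaperone cofactor gene SDF2L1 by −0.66. Of 22 p53 targets 6 rose and 4 fell (7 and 5 adjusted over the list alone, adjusted p = 0.327), with SESN1 at 0.83 and PPM1D at 0.74. Of 17 heat shock genes 5 rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.34), with the small heat shock protein gene CRYAB at 0.66 and FKBP4 at −0.67. Of 18 cholesterol synthesis genes 3 rose and 2 fell (3 and 4 adjusted over the list alone, adjusted p = 0.708); the list median was −0.10 and its mean 0.00298. Of 36 oxidative phosphorylation genes 2 rose and 2 fell (1 and 1 adjusted over the list alone, adjusted p = 0.508).

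A hypothesis was that genes raised by erastin in siNT cells depend on TAZ and are lower with siTAZ in vehicle. Of the 63 raised genes, 37 (58.7%) had a negative siTAZ effect, 29 were called lower and 20 higher, with a median of −0.12. Both comparisons use the same siNT vehicle arrays, and 100 simulations with this sharing and without a siTAZ effect gave 31.7% to 56.7% (median 44.5%). The observed share lies above that range, but as the sharing lowers the share, this is no test of the sharing as the source of a high one. Random sets matched on mean level, 10000 in number, gave 38.1% to 61.9%, but do not carry that sharing. A further 1000 simulations did, and gave each gene the siTAZ effect of another gene of like level. They gave 35.2% to 61.6% (median 48.3%), or 32.7% to 60.0% with only called effects kept, and 5.9% and 3.5% of them reached the observed share. The observed share lies within both ranges, so the finding is negative: the raised genes as a whole were not shown to be lower more often than other genes of their level. Of the raised genes 24 are in the ATF4 list. Of the 39 others 15 were negative, 9 were called lower and 19 higher, with a median of 0.17.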
